A study of Mus musculus with 47 samples.

How the data were processed

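RNA from PFC and hippocampus was extracted with RNeasy kits, polyadenylated RNA was made into libraries with the TruSeq Stranded mRNA kit, and 52-bp paired-end reads were sequenced on a NovaSeq 6000, per the labels' protocols. Reads were converted with bcl2fastq 2.20.0 and handled with STAR and Salmon against the mouse genome build GRCm38, per the submitters' processing notes; the versions of STAR and Salmon are not given in the sources used here. The deposited tables hold an estimated count per gene (45706 genes) and per transcript (109617 transcripts) in each of 47 libraries, made by the authors before any scaling between libraries. All 47 sample columns of both tables were used and 0 were left out. Estimated counts were rounded to whole numbers before testing. The gene symbols come from the deposited table, in which 92 symbols stand on more than 1 line.

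The labels gave tissue, treatment and replicate number for each library, and the groups follow them: 24 PFC libraries, 8 for each of the 3 treatments, and 23 hippocampal libraries, 7 for saline and 8 for each inhibitor. The groups labelled PICK1i and PSD-95i were matched to the compounds mPD5 and UCCB01-147 of the protocol from general knowledge of these compounds. Mean total counts were 8.77, 7.63 and 8.29 M in PFC and 8.34, 8.95 and 9 M in hippocampus (M, mega) for saline, PICK1i and PSD-95i. The mean share of mitochondrially encoded transcripts was 9.97, 10.5 and 9.68% in PFC and 9.52, 10.5 and 10% in hippocampus, in the same order.

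Each tissue was fitted apart, with its 3 groups in 1 model, and all 6 groups were fitted together for the difference of a drug effect between tissues and for hippocampus against PFC. The test was edgeR's quasi-likelihood F test (version 4.0.16, robust, two-sided) with TMM scaling and filterByExpr (minimum count 10, minimum total 15), and Benjamini-Hochberg adjusted p under 0.05 was called. The 4 comparisons of a drug with saline ask what each inhibitor changed, and the comparison between inhibitors asks where they differed as dosed. Levels are CPM (counts divided by the TMM-scaled library total in M), with a prior count of 2 on the log2 scale, and list scores are the mean log2 CPM of a list's genes. The software was R 4.3.3 and Python 3.11.15 with matplotlib 3.10.9. Gene positions and exon overlaps come from GENCODE release M21 on GRCm38, which held 45143 of the table's gene IDs.

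There were 45 gene lists, 23 of processes and 22 of cell types or regions that the dissected pieces could hold, with 962 genes, of which 958 were in the table and 4 were not matched. Each list with at least 5 tested members went through camera of limma 3.58.1 on voom-weighted values with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. Members with too few counts in a tissue were not tested there. Among the lists called, median, mean and test had the same sign.

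The genes, lists, tests and the naming rule were fixed before the data were examined, apart from the tests named below as added or chosen later. The rule named Pick1 and Dlg4 in every drug and saline comparison, the 10 called genes with the smallest p in each direction, up to 3 further called members of each list, and 3 members of each called list in its direction. Where fewer than 10 genes passed, the 10 with the smallest p were named as values. Between inhibitors and for tissue differences of an effect it named 5 genes per direction, and for hippocampus against PFC 2 members of each regional list. Predicted gene models were counted and not named. Not every gene that the rule names is printed.

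Alternatives were RLE scaling, no filter beyond 1 count, a filter of at least 1 CPM, DESeq2 1.42.0, limma voom with sample quality weights, transcript counts, only the groups compared, 2 surrogate variables from sva 3.50.0, a block on replicate number, an adjusted p under 0.1, and leaving out each library in turn. Added after the data were seen were a fit without 5 libraries high in markers of another region, 2 principal components of the marker scores as covariates, neighbouring replicate numbers summed, and PFC marker scores without saline replicate 1. The test of the immediate early list across tissues was also added then. The same-control likeness of the inhibitors was set against 1000 simulated draws of unchanged groups. Other splits of the libraries were drawn 100 times per comparison, score differences between groups were tested by exact permutation and score correlations by 100000 permutations.

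All fits were tested on simulated data with 200 changed genes. Of genes changed 1.5-fold, the recovered share was 71.6% for PICK1i against saline in PFC (14911 genes), 76.1% for PSD-95i, 70.1% and 59.7% in hippocampus (15051 genes), and 53.7% and 41.8% for the differences of effect between tissues (15658 genes). Of genes changed 2-fold, the shares were 91, 95.5, 89.6, 88.1, 76.1 and 76.1% in the same order. The simulated genes varied independently of each other, with 200 genes and 1 whole list changed together. No simulated library held tissue of another region. Recovery in the real comparisons may therefore be lower than these shares. Smaller changes, or changes in few cells, could be missed at this depth and group size.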

Results

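Polyadenylated RNA was sequenced from prefrontal cortex (PFC) and hippocampus of mice with diet-induced obesity after injections of saline or of an inhibitor of PICK1 or PSD-95. Both proteins carry PDZ domains and bind glutamate receptors, PSD-95 (gene Dlg4) in the postsynaptic density and PICK1 (gene Pick1) during receptor trafficking. The inhibitors named in the labels' protocol are mPD5, known as a PICK1 inhibitor and given at 56 mg/kg, and UCCB01-147, known as a PSD-95 inhibitor and given at 25 mg/kg. Injections were given daily for 5 days, and tissue was taken 2 hours after the last one. The study's stated purpose was to compare the expression profiles of these brain regions between treatments. There were 8 libraries per group in PFC, and in hippocampus 7 for saline, 8 for PICK1i (the PICK1 inhibitor group) and 8 for PSD-95i (the PSD-95 inhibitor group). The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples. Total estimated counts per library ran from 5434485 to 12673672 in PFC and from 5378174 to 13139408 in hippocampus. No libraries of 1 group were alike within counting noise. The smallest chi-square per gene between members of a group ran from 3.04 to 4.15. The protocol in the labels speaks of whole hypothalamus and of 6 saline mice, which matches neither the tissues nor the saline groups analysed here. Whether its doses, times and housing hold for these samples is therefore uncertain.

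Transcripts of the inhibited proteins did not differ detectably between treatments. In PFC, Pick1 (chromosome 15, 79229173 to 79249484) measured 48.7 ± 3.84 CPM (SD, n = 8) after saline, 51.1 ± 5.37 CPM (n = 8) after PICK1i and 49.9 ± 4.11 CPM (n = 8) after PSD-95i. Dlg4 (chromosome 11, 70016942 to 70047522) measured 1000 ± 51.4 CPM after saline, 1060 ± 116 CPM after PICK1i and 986 ± 39.8 CPM after PSD-95i, with n = 8 each. In hippocampus, Pick1 measured 44.4 ± 3.37 CPM after saline (n = 7), 46.3 ± 5.5 CPM after PICK1i and 43.7 ± 6.37 CPM after PSD-95i (n = 8 each), and Dlg4 measured 1040 ± 48.5, 963 ± 154 and 1030 ± 84.2 CPM in the same order. PICK1i replicate 7 of hippocampus held 598 CPM of Dlg4, and without it the PICK1i mean was 1010 ± 50.1 CPM (n = 7). The log2 fold changes of Pick1 against saline were 0.07 and 0.04 in PFC and 0.06 and -0.03 in hippocampus, for PICK1i and PSD-95i, and those of Dlg4 were 0.08, -0.03, -0.11 (-0.03 without that library) and -0.01. Adjusted p was 0.95 or more for all 8 of these values in edgeR's quasi-likelihood test. Exons of Pick1 overlap those of the predicted gene Gm49486 on the same strand, so its reads could be divided between them. Both compounds act on protein binding, so transcript levels do not test whether the targets were reached.

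In PFC, a set of immediate early genes was higher after PICK1i than after saline. These are the genes that neurons switch on within minutes to hours of activity. Arc, which encodes a cytoskeletal protein of active synapses, rose 2.93-fold, from 114 ± 23.6 to 333 ± 70.4 CPM (SD, n = 8 each), a log2 change of 1.55 with a standard error of 0.16 (edgeR, adjusted p = 4.22e-06). The nuclear receptor gene Nr4a1 rose 1.94-fold, from 77.1 ± 11.9 to 149 ± 26.9 CPM (adjusted p = 2.17e-06). Junb and Fos, which encode subunits of the AP-1 transcription factor, rose 1.9-fold and 2.23-fold (adjusted p = 4.22e-06 and 0.000901). The phosphatase gene Dusp5 rose 2.07-fold and Gpr3, which encodes a constitutively active receptor, rose 1.92-fold (adjusted p = 0.000316 for both). For Arc, Nr4a1 and Junb, each of the 8 PICK1i libraries lay above every saline library. The lowest PICK1i value of Arc was 239 CPM against a highest saline value of 157 CPM. Levels after PSD-95i were 122 ± 32.8 CPM for Arc, 72.3 ± 7.59 CPM for Nr4a1 and 9.37 ± 2.6 CPM for Fos (n = 8).

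Of 14911 genes tested in PFC, 30 passed an adjusted p of 0.05 for PICK1i against saline, 27 higher and 3 lower, with a median absolute log2 change of 0.53. Unadjusted p was under 0.05 for 852 genes, against 746 expected by chance. Further genes that rose were Midn, Trib1, Sik1, Ier2 and Dusp1 (1.46, 1.49, 1.7, 1.8 and 1.67-fold), Nab2, a corepressor of Egr proteins (1.35-fold), and the heat shock protein gene Dnajb5 (1.33-fold). The clock genes Per1 and Per2 rose 1.46-fold and 1.27-fold. Ptpn1, which encodes a phosphatase that limits insulin and leptin receptor signalling, rose 1.27-fold. The genes that fell were Rasgef1b, by 0.42 on the log2 scale from 67.4 ± 4.08 to 50.3 ± 5.94 CPM, the sphingosine 1-phosphate receptor gene S1pr3, by 0.37, and the unnamed model 1190002N15Rik, by 0.45 (adjusted p = 0.000545, 0.0479 and 0.0353). The last of these lay outside the naming rule and was chosen after its values were seen. DESeq2 called 47 genes (41 higher, 6 lower), with all 30 among them, and a fit with 2 surrogate variables called 61. The count dropped to 19 without saline replicate 2. The call of S1pr3 held only when PICK1i replicate 2 or 6 or PSD-95i replicate 4 was the library left out, that of Per2 only when it was PICK1i replicate 1, 2 or 6 or saline replicate 3 or 7. Beyond single libraries, the calls of S1pr3, Per2 and Ptpn1 ended in 7, 4 and 4 of 13 alternatives. With neighbouring replicate numbers summed, Fos and Dusp1 were not called (adjusted p = 0.113 and 0.0788), nor was Dusp1 with transcript counts (0.0758), and over all settings adjusted p ran from 1.33e-07 to 0.113 for Fos and from 1.52e-05 to 0.0788 for Dusp1. The call of Ptpn1 ended without any of saline replicates 1, 2, 4, 5, 6 and 8 and PICK1i replicates 4, 5 and 7. Exons of Junb, Dusp1, Dusp5, Gpr3, Nab2 and S1pr3 overlap those of a gene on the other strand. The library kit marks strand, but the strand setting of the counting is not given in the sources used here.

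Of the 53 measured immediate early genes, a list fixed beforehand, 17 rose in PFC after PICK1i, 0 fell and 36 did not pass, and 47 had a positive log2 change (median 0.43). Adjusted over the list alone, 31 were higher and 1 was lower, the sortilin-related receptor gene Sorcs3 (log2 change -0.21). It was named after its value was seen. Camera, limma's competitive set test, gave an adjusted p of 2.13e-49 with its preset correlation, and adjusted p = 4.28e-06 with an estimated correlation. The preset setting calls this list readily. It did so in 58 of the other splits of these libraries, with a smallest camera p of 4.29e-20 among them. Of the 35 glucocorticoid-responsive genes, 2 rose (Per1 and Dusp1, which the immediate early list also holds), 0 fell and 33 did not pass, 7 were higher adjusted over the list alone, and the median was 0.13. Of the 21 clock genes, 2 rose (Per1 and Per2) and 19 did not pass (3 higher adjusted over the list alone). The camera adjusted p of the clock list was 0.0943. Of the 30 genes of leptin, insulin and melanocortin signalling, 1 rose (Ptpn1) and 29 did not pass, with 1 higher adjusted over the list alone and a camera adjusted p of 0.197.

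Camera called 6 of 41 lists in this comparison with the preset correlation, and only the immediate early list held with an estimated one. The others were the glucocorticoid list and the 14 inflammatory cytokine and acute phase genes, both higher, and 3 lower lists, the 24 cholesterol synthesis and uptake genes (median -0.09), the 14 oligodendrocyte markers (median -0.21) and the 11 striatal neuron markers (median -0.91). The oligodendrocyte call ended with composition components (adjusted p = 0.187). No member of the last 4 lists passed over all genes. Adjusted over the list alone, counts were 2 higher inflammatory genes, 1 lower cholesterol gene, 0 oligodendrocyte markers and 4 lower striatal markers. Adjusted p = 0.294 with an estimated correlation for the glucocorticoid, inflammatory and cholesterol lists, 0.513 for oligodendrocyte and 0.505 for striatal markers. The enzyme gene Sqle measured -0.25 on the log2 scale (adjusted p = 0.308), Socs3, a feedback inhibitor of cytokine and leptin signalling, 0.51 (0.588), Osmr 0.46 (0.559), and the myelin gene Cnp -0.22 (0.761). The striatal score of saline replicate 1 was 5.72 (mean log2 CPM), against 2.96 to 4.22 in the other saline libraries. PICK1i replicate 6 had an olfactory bulb and tubercle score of 6.06, against 1.07 to 1.87 in the other PICK1i libraries. Without these libraries 33 genes were called (29 higher, 4 lower), and the cholesterol list was not (adjusted p = 0.0957). The list count rose to 14, 11 and 12 without PICK1i replicates 1, 3 and 7, and to 11 without saline replicate 4.

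After PSD-95i, myelin genes and deep-layer cortical genes had lower values in PFC, but no single gene passed. The 14 oligodendrocyte markers all had negative log2 changes (median -0.40), among them Gjc3 (-0.45, standard error 0.09), Cldn11 (-0.43) and Mal (-0.42), with 13 lower adjusted over the list alone. The 15 deep-layer markers were all negative too (median -0.52), with Tle4 at -0.52, Hs3st4 at -0.78 and Rprm at -1.05, and 5 were lower adjusted over the list alone. Superficial-layer markers had the other sign (11 measured, 10 positive, median 0.23), with Cux2 at 0.31. None of these members passed over all genes, and adjusted p was 0.32 for Gjc3 and 0.651 or less for the others named. Mean oligodendrocyte scores were 6 ± 0.24 after saline, 5.8 ± 0.26 after PICK1i and 5.63 ± 0.21 after PSD-95i (mean log2 CPM, SD, n = 8), and mean deep-layer scores 4.42 ± 0.4, 4.22 ± 0.28 and 3.83 ± 0.44.

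edgeR called 0 of 14911 genes for PSD-95i against saline in PFC, with a smallest adjusted p of 0.32. Unadjusted p was under 0.05 for 946 genes against 746 expected, limma voom with sample weights called 0, and DESeq2 called 2, both lower, Zfpm2 (-0.81, adjusted p = 0.0192) and Gjc3 (-0.44, adjusted p = 0.0433). Without saline replicate 4, edgeR called 2 genes, again Zfpm2 and Gjc3 (adjusted p = 0.0486 for both). In the main edgeR test the log2 changes with the smallest p were Zfpm2 (-0.81), Gjc3, Tgfb3 (-0.32), Stc1 (0.66), Tmem88b (-0.50), Lrg1 (0.82), Cldn11, Unc5b (-0.48), Adamtsl2 (-0.75) and Hhip (-0.97), the first 2 at an adjusted p of 0.32 and the others above it. The 53 immediate early genes had a median of -0.06 with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.162).

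Camera called 13 of 41 lists for PSD-95i in PFC, 5 higher and 8 lower, and none held with an estimated correlation. Adjusted p = 0.133 with an estimated correlation for oligodendrocyte and for deep-layer markers, and 0.172 for superficial-layer markers. The 28 interferon-stimulated genes were higher (26 positive, median 0.24, Rtp4 at 0.54), and the 24 cholesterol genes (median -0.10, Msmo1 at -0.23, 1 lower adjusted over the list alone), the 11 striatal markers (median -1.29, Adora2a at -1.69, 7 lower adjusted over the list alone), and the 14 CA2 and CA3 pyramidal cell markers (median -0.14, Pcp4 at -0.66, 1 higher and 2 lower adjusted over the list alone) were lower. Adjusted p = 0.338, 0.286, 0.314 and 0.251 with an estimated correlation for these 4 lists. The striatal score of saline replicate 1 was 5.72 against 2.96 to 4.22 in the other saline libraries, and without it Adora2a measured -0.79 and the mean difference of striatal scores was -0.48 in place of -0.76. The remaining 6 were the glucocorticoid (median 0.08, 1 higher adjusted over the list alone), clock (0.07) and leptomeningeal (0.16) lists, higher, and the ionotropic glutamate receptor (-0.06), oligodendrocyte precursor (-0.14) and microglial (-0.11) lists, lower, with adjusted p between 0.278 and 0.701 with an estimated correlation. With 2 surrogate variables, and likewise with 2 composition components, the oligodendrocyte, deep-layer, cholesterol, striatal and microglial lists kept their calls. The superficial (adjusted p = 0.0917 and 0.0944), interferon (0.525 and 0.163) and CA2 and CA3 (0.835 and 0.111) lists and the other 5 did not keep call and direction. Each of the 6 remaining lists lost its call when 1 library was left out. The glucocorticoid list did so without PSD-95i replicate 7 (adjusted p = 0.174), the microglial list without saline replicate 6 (0.0522), the clock list without saline replicate 6 or PSD-95i replicate 4 (0.062 and 0.0949), and the precursor list without saline replicate 6 (0.107) or 3 or PSD-95i replicate 3 or 4. The leptomeningeal list did so without saline replicate 1 (0.275), 5 or 7 or PSD-95i replicate 4 or 7, and the glutamate receptor list without saline replicate 1 (0.169), 2 or 3 or PSD-95i replicate 2, 4, 7 or 8.

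Between the inhibitors in PFC, the immediate early list had the smallest camera p. Relative to PICK1i, PSD-95i libraries had lower Arc (by 1.45 on the log2 scale, or -1.45 with a standard error of 0.16), Nr4a1 (-1.05), Junb (-0.95), Trib1 (-0.78) and Midn (-0.49), with edgeR adjusted p from 3.13e-07 to 2.69e-05. Of the 53 list members, 22 fell and 0 rose, and 34 were lower and 1 higher adjusted over the list alone (median -0.43, camera adjusted p = 2.87e-45, adjusted p = 8.84e-06 with an estimated correlation). Rasgef1b rose 1.33-fold, Net1, a RhoA exchange factor gene, 1.42-fold, AI593442 1.43-fold, the transcription factor gene Nr2f1 1.28-fold and Wnt9a 1.39-fold, with adjusted p of 0.013 or less. With neighbouring replicate numbers summed the calls of Net1, AI593442, Nr2f1 and Wnt9a ended, and those of Net1, Nr2f1 and Wnt9a also with transcript counts, with adjusted p over all settings up to 0.107, 0.0825, 0.206 and 0.107 in that order of 4 genes. Surrogate variables ended the calls of Net1 and Wnt9a, and a fit of only the groups compared that of Wnt9a. In all, 50 of 14911 genes passed, 11 higher and 39 lower after PSD-95i, with 1431 at an unadjusted p under 0.05. By the labels' protocol, whose match to these samples is uncertain, the doses differed, 56 against 25 mg/kg, so this compares the treatments as given. DESeq2 called 98 genes (38 higher, 60 lower), and edgeR called 83 without PSD-95i replicate 6.

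The other lists called between the inhibitors in PFC were the glucocorticoid list (35 genes, 2 fell, 3 lower adjusted over the list alone, median -0.07), the oligodendrocyte (median -0.20), microglial (-0.11) and deep-layer (-0.41, 1 lower adjusted over the list alone) markers, lower, 5 red blood cell markers, lower (median -0.61, 4 lower adjusted over the list alone), and the interferon-stimulated genes (0.20) and superficial-layer markers (0.23), higher. That makes 8 of 41 lists, and apart from the immediate early list none held, with adjusted p = 0.66 to 0.964 with an estimated correlation. The glucocorticoid list lost its call without PSD-95i replicate 1 (adjusted p = 0.187) or 2 or PICK1i replicate 5 or 8, the oligodendrocyte list without PICK1i replicate 1 (0.086), and the microglial list without PICK1i replicate 1 (0.142), 5 or 8 or PSD-95i replicate 3, 6 or 8. Surrogate variables ended the calls of the interferon (0.419), oligodendrocyte (0.24), superficial (0.651) and deep-layer (0.519) lists.

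In hippocampus, no gene passed for PICK1i against saline, and markers of neighbouring regions varied between libraries. Arc measured 115 ± 70.6 CPM after PICK1i and 115 ± 24 CPM after saline, and Nr4a1 65.7 ± 37.4 and 62.5 ± 14.1 CPM (SD, n = 8 and 7). PICK1i replicate 2, which was high in striatal markers, raised both PICK1i means. It held 273 CPM of Arc and 154 CPM of Nr4a1, against 28.7 to 125 and 33.3 to 65.3 CPM in the other PICK1i libraries. The thalamic marker Slc17a6, a vesicular glutamate transporter gene, averaged 58.3 ± 110 CPM after PICK1i and 11.6 ± 8.68 CPM after saline, with a highest PICK1i value of 329 CPM. The largest values among thalamic markers were log2 changes of 2.29 for Slc17a6, 2.07 for Tcf7l2 and 1.76 for Synpo2, each at an adjusted p of 0.956. PICK1i replicate 7 had a thalamic score of 7.33 (mean log2 CPM), against 3.34 to 4.75 in the other PICK1i libraries, and an excitatory neuron score of 4.5 against 7.7 to 8.04. Without it Slc17a6, Tcf7l2 and Synpo2 measured 0.74, 0.14 and 0.18.

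edgeR called 0 of 15051 genes for PICK1i in hippocampus, with a smallest adjusted p of 0.956 and 580 genes at an unadjusted p under 0.05 (753 expected). DESeq2 and limma voom also called 0, and 0 were called without saline replicate 1 and PICK1i replicates 2 and 7, which were high in striatal or thalamic markers. The smallest p belonged to Rab23 (log2 change 0.23), Xdh (0.41), Hey1 (-0.20), Maff (1.12), Tead3 (0.73), Nostrin (0.52), Dnajc28 (0.27), Gvin1 (0.87), Sepn1 (0.29) and Commd6 (0.31). The 54 immediate early genes had a median of 0.03, with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.704).

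Camera called 15 of 43 lists for PICK1i in hippocampus, 11 higher and 4 lower, and none held with an estimated correlation. The 4 lower lists were the PSD-95 and PICK1 scaffold partners (41 genes, median -0.09, Nlgn1 at -0.27), the BDNF, CREB and CaMK signalling genes (31 genes, median -0.10, Bdnf at -0.35), the excitatory neuron markers (10 genes, median -0.24, Slc17a7 at -0.23) and the dentate gyrus markers (15 genes, median -0.19, Il16 at -0.45). The thalamic and habenular markers (11 genes, median 1.22, 9 higher adjusted over the list alone), the glucocorticoid list (35 genes, median 0.13, 1 higher adjusted over the list alone) and the 73 nuclear oxidative phosphorylation genes (64 positive, median 0.07) were higher. Adjusted p = 0.614 to 0.81 with an estimated correlation for these lists. Without PICK1i replicate 7, the calls of the scaffold (adjusted p = 0.118), BDNF (0.0558), excitatory (0.0867), thalamic (0.39) and heat shock (0.266) lists ended, and the oxidative phosphorylation list turned lower (0.0363). The dentate call ended without PICK1i replicate 2 (0.0774), and the thalamic call also without saline replicate 2 or PICK1i replicate 8.

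The remaining higher lists for PICK1i in hippocampus were mitochondrially encoded genes (median 0.12), heat shock (0.07), interferon-stimulated (0.12), astrocyte (0.10), endothelial (0.11), pericyte (0.14), red blood cell (0.18) and olfactory (0.29) lists, with adjusted p = 0.614 to 0.642 with an estimated correlation. The interferon list lost its call without saline replicate 2 or PICK1i replicate 5 (adjusted p = 0.0598 and 0.0929), and the pericyte list without those (0.0598 and 0.31) or saline replicate 6. The astrocyte list did so without PICK1i replicate 5 (0.159), 4 or 6 or saline replicate 1, 2 or 7. The red blood cell list did so without saline replicate 2 (0.241), 4, 6 or 7, PICK1i replicate 2, 5, 6, 7 or 8 or PSD-95i replicate 2, 7 or 8, and the olfactory list without PICK1i replicate 5 (0.106), 4, 6 or 8 or saline replicate 3, 6 or 7.

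**Figure D1:**
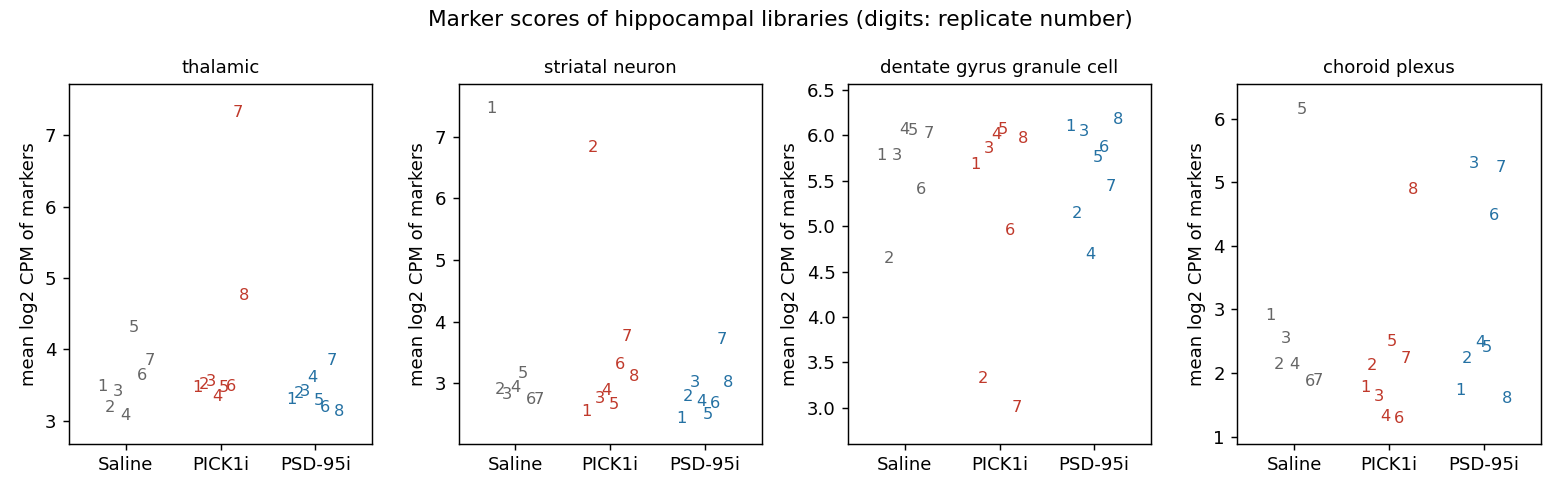
Scores of regional marker lists in the 23 hippocampal libraries, as mean log2 CPM of the list's genes, one point per library by treatment. PICK1i replicate 7 stood at 7.33 for thalamic and habenular markers, and saline replicate 1 and PICK1i replicate 2 at 7.46 and 6.82 for striatal markers.

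For PSD-95i against saline in hippocampus, the largest values were in striatal markers, and they came with 1 saline library. Drd2, a dopamine receptor gene, averaged 1.93 ± 0.877 CPM after PSD-95i (n = 8) and 16.2 ± 36.5 CPM after saline (n = 7), where the highest library held 99 CPM. Its log2 change was -3.03, and those of Drd1 and Syndig1l were -2.06 and -2.05, each at an adjusted p of 1. The striatal score of saline replicate 1 was 7.46, against 2.73 to 3.16 in the other saline libraries, and without it Drd2, Drd1 and Syndig1l measured -0.29, -0.31 and -0.22. edgeR called 0 of 15051 genes, with 231 at an unadjusted p under 0.05 (753 expected), and DESeq2 and limma voom called 0. The smallest p belonged to Smtnl2 (-0.89), Ifitm2 (0.56), Sema3d (0.57), Ankrd37 (-0.72), Timm9 (0.34), Gpr157 (-0.56), Dmp1 (0.37), Fdxacb1 (-0.42), Tatdn1 (0.35) and Tmem62 (-0.21).

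Camera called 6 of 43 lists for PSD-95i in hippocampus, and none held with an estimated correlation. Higher were the 35 glucocorticoid-responsive genes (28 positive, median 0.09, Xdh at 0.31), 15 mitochondrially encoded genes (median 0.08), 31 extracellular matrix and collagen genes (25 positive, median 0.16, Mmp14 at 0.17) and 12 leptomeningeal markers (median 0.30, Ogn at 0.61). Lower were 5 red blood cell markers (median -0.37) and 12 striatal markers (median -2.05, 9 lower adjusted over the list alone). Adjusted p was 0.688 to 0.83 with an estimated correlation. The striatal call ended without saline replicate 1 (adjusted p = 0.759), the leptomeningeal call without PSD-95i replicate 7 (0.305) or 3 or saline replicate 7, and the red blood cell call without saline replicate 5 (0.259) or 3 or PSD-95i replicate 1 or 3. The list count rose to 11 without saline replicate 2 or PSD-95i replicate 2 and to 10 without saline replicate 5.

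Between the inhibitors in hippocampus, no gene passed. Nostrin, an endothelial regulator of nitric oxide synthase, measured -0.71 (standard error 0.145) for PSD-95i against PICK1i, Hmcn1 -0.85, Ccdc117 -0.29, Rbm43 -0.31 and the vascular receptor gene Flt1 -0.21, at adjusted p of 0.724 for the first 2 and 0.9 for the rest. edgeR called 0 of 15051 genes with 734 at an unadjusted p under 0.05 (753 expected), and DESeq2 and limma voom called 0. Of 43 lists, camera called 16, 6 higher and 10 lower, and none held with an estimated correlation. They included endothelial (16 genes, median -0.14), hypoxia (20 genes, -0.08), red blood cell (-0.55) and thalamic markers (-1.61), lower, with 1, 0, 1 and 9 genes lower adjusted over the list alone, and choroid plexus (1.01), excitatory (0.25), dentate (0.19), CA1 (0.20) and scaffold partner (0.10) lists, higher, with adjusted p = 0.204 to 0.74 with an estimated correlation. The mean thalamic score was 4.11 after PICK1i, 3.65 without its replicate 7 (7.33), and 3.39 after PSD-95i. The thalamic call held without that library (adjusted p = 0.00965) and ended with surrogate variables (0.479) and with composition components (0.556). The count was 9 without PICK1i replicate 7, where the excitatory (adjusted p = 0.167), CA1 (0.505) and scaffold (0.0802) calls ended. The dentate call ended without PICK1i replicate 2 (0.0984) and the choroid plexus call without PSD-95i replicate 7 (0.0756).

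The effect of PICK1i on Per1 differed between the tissues. Per1 measured 173 ± 9.23 and 253 ± 24.1 CPM after saline and PICK1i in PFC (SD, n = 8 each) and 129 ± 8.46 and 130 ± 18.5 CPM in hippocampus (n = 7 and 8). The difference of log2 changes, hippocampus minus PFC, was -0.54 with a standard error of 0.10 (edgeR, adjusted p = 0.0282), and Per1 was the only 1 of 15658 genes called, with 605 at an unadjusted p under 0.05 (783 expected). Arc measured -1.55 (adjusted p = 0.148), Dusp5 -0.98 (0.281) and Per2 -0.47 (0.429), and Stoml3, an olfactory gene, -7.32 (0.202). PFC PICK1i replicate 6 had an olfactory score of 6.06 against 1.07 to 1.87 in the other libraries of its group, and without it Stoml3 measured -3.54 (adjusted p = 1). The 54 immediate early genes had a median difference of -0.39 (8 positive, 1 lower over all genes, 13 lower adjusted over the list alone), with a camera adjusted p of 1.44e-21 and adjusted p = 0.000502 with an estimated correlation. That list test across tissues was added after the results within each tissue were seen. The Per1 call ended in 20 of 47 omissions of 1 library, with adjusted p up to 0.389 over the other settings. These libraries were saline replicates 1, 2, 4, 5, 6, 7 and 8 and PICK1i replicates 3, 4, 5, 7 and 8 of PFC, and saline replicates 1, 5, 6 and 7 and PICK1i replicates 1, 3, 4 and 5 of hippocampus. edgeR called 8 genes without hippocampal PICK1i replicate 2 and 9 without the 5 libraries high in markers of another region, Arc among them both times (adjusted p = 0.00044 and 0.000739), DESeq2 called 2 (Per1 and Arc) and limma voom 10.

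For PSD-95i, no gene's effect differed detectably between the tissues. edgeR called 0 of 15658 genes, with 428 at an unadjusted p under 0.05 (783 expected), and DESeq2 and limma voom called 0. The smallest p belonged to Cpt1b (-1.66), which encodes a fatty acid transporter enzyme of mitochondria, Zfpm2 (0.97), Dennd6a (0.22), Acbd3 (0.23) and Abca8a (0.67), each at an adjusted p of 1. The 15 deep-layer markers had a median difference of 0.40 and the 14 oligodendrocyte markers of 0.29, with camera adjusted p of 8.93e-06 and 0.00246, and adjusted p = 0.292 and 0.989 with an estimated correlation.

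**Figure D2:**
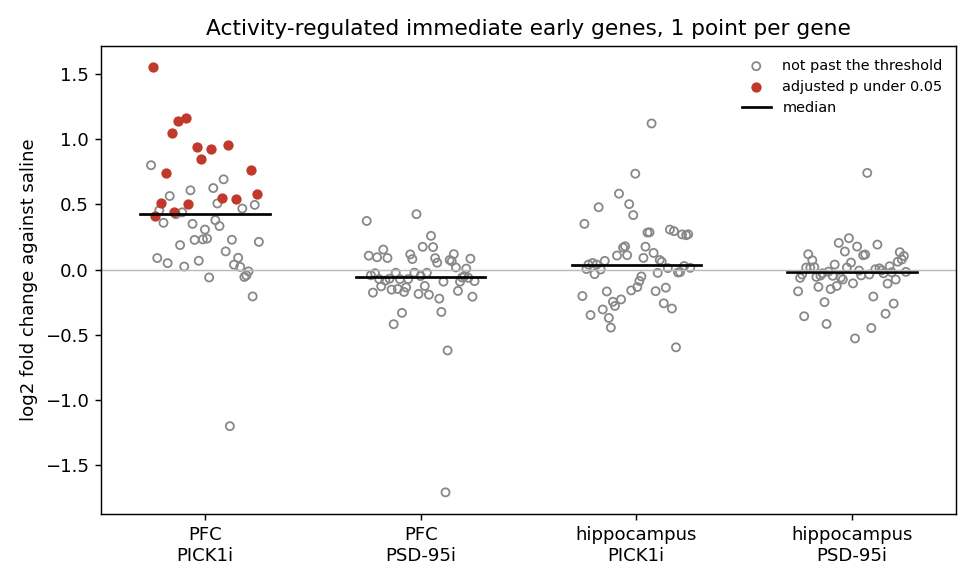
Log2 fold change against saline of each measured immediate early gene in the 4 comparisons of a drug with saline, one point per gene and a bar at the median. The median was 0.43 for PICK1i in PFC, -0.06 for PSD-95i in PFC, 0.03 for PICK1i in hippocampus and -0.02 for PSD-95i in hippocampus.

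As groups, the saline libraries of the tissues differed as their labels state. C1ql2, a dentate granule cell gene, was 198-fold higher in hippocampus and Fibcd1, a CA1 gene, 12.8-fold, while Lamp5 and Pou3f2 of superficial cortex were lower, with log2 changes of -2.63 and -1.91 (edgeR, adjusted p from 5.46e-14 to 6.4e-15 for C1ql2, Fibcd1 and Lamp5). Of 15658 genes, 5994 passed, 3050 higher and 2944 lower in hippocampus. In the dentate list 10 of 15 genes were higher and 0 lower, and of 11 superficial-layer genes 7 were lower and 1 higher. Camera called the superficial list with either correlation (adjusted p = 2.3e-05, and adjusted p = 0.0375 with an estimated correlation). The dentate, oligodendrocyte and choroid plexus lists were higher (median 2.10, 0.93 and 4.24), with adjusted p = 0.67 or less with an estimated correlation (0.666 for the first 2). The choroid plexus score of hippocampal saline replicate 5 was 6.15, against 1.87 to 2.91 in the other hippocampal saline libraries. The CA1 score of hippocampal saline replicate 1 was 4.54, against 5.61 to 6.41 in the others of that group. Values of striatal genes depended on single saline libraries. Rgs9 was called higher (log2 change 1.71, adjusted p = 0.0305), but measured -0.30 without hippocampal saline replicate 1 (adjusted p = 0.701) and -0.30 in DESeq2 (0.463). Syndig1l (1.91) measured 0.08 without that library (0.943) and 3.09 without PFC saline replicate 1 (0.000933). With a block on replicate number, edgeR called neither Rgs9 (1.225, adjusted p = 0.0972) nor Syndig1l (1.633, 0.0528).

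Over all genes in PFC, the log2 changes of the inhibitors against saline had a Pearson correlation of 0.428 and a covariance of 0.00978, and 61.7% of 14911 genes had the same sign. Genes are not independent replicates, and both comparisons use the same saline libraries. Simulated unchanged groups were made by shuffling the residuals of all libraries of the tissue, saline included, over the 3 groups. They share a control group as the real comparisons do, but not the real saline libraries. On average they gave a correlation of 0.489, a covariance of 0.00963 and 66.4% of genes with the same sign. The observed covariance exceeded the simulated one by 0.000152, and 446 of 1000 draws had a covariance as high. With the saline libraries divided in 2 sets of 4, one per inhibitor, the correlation was 0.077 on average over 70 divisions. In hippocampus the correlation was 0.316 against 0.53 simulated, the covariance 0.00742 against 0.0174, and the divided saline libraries gave -0.142.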

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

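The tests on hippocampal PICK1i replicate 7 and on oligodendrocyte and deep-layer markers were chosen after those patterns were seen. So were the fits with composition covariates and with neighbouring replicate numbers summed, and the test of the immediate early list across tissues. The splits were set before. The expectations for the immediate early genes were written before their tests were run. They name PFC PICK1i replicate 6, so the marker scores had been seen by then.

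The first pattern is the higher level of immediate early genes in PFC after PICK1i. Of the 100 splits of the PICK1i and saline libraries, 1 gave as many called genes, the real one with 30 against a highest other count of 2, and 1 gave as small a list p (5.2e-51, next 4.29e-20), which argues against a chance division of these libraries. Without PICK1i replicate 6, whose olfactory score stood apart, 25 of the 27 genes called higher kept their call (median log2 change 0.56), and with 2 composition components the median was 1.02 times the main one, which argues against stray tissue or a different make-up of the pieces as the whole cause. By the labels' protocol mice were housed in pairs. Neighbouring numbers were summed as if they were cage mates, which leaves 4 units per group. Of the 27 genes, 14 kept their call. That just met the bound written before that test, at least 14, which was to count against an effect of shared cages. The median log2 change of all 27 was 0.538 against 0.545. Summing within a group keeps the change nearly the same, so this cannot tell an effect of shared cages from the loss of units. The labels do not say which mice shared a cage, so the question stays open. An effect of the inhibitor may account for the pattern, and so might handling or the clock time of sacrifice if these went with the groups. The labels give 1 protocol for every group, which lists injection 2 hours before dark and tissue taken 2 hours after a last injection. They give no times per mouse, and no test here addressed handling or clock time.

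The second pattern is the set of scores of PICK1i replicate 7 in hippocampus. Its thalamic score was 7.3 on the scale of all libraries, and its dentate, CA1 and excitatory scores 2.99, 3.57 and 4.48, so that 4 of 4 lay outside the other hippocampal libraries in the direction of thalamus. These scores restate the pattern and test no cause, so thalamic tissue in the dissected piece may be its source but is not established by them, and the same holds for the marker genes Slc17a6 (329 CPM) and Tcf7l2 (173 CPM). Its superficial-layer score of 5.22 lay under the lowest PFC score of 6.23, which argues against a swap with a PFC library. No biological explanation was tested.

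The third pattern is the lower oligodendrocyte and deep-layer marker level in PFC after PSD-95i. The exact two-sided permutation test on scores gave a difference of -0.37 (standard error 0.11, p = 0.0081) for oligodendrocyte, -0.59 (standard error 0.21, p = 0.016) for deep-layer and -0.76 (standard error 0.32, p = 0.0082) for striatal markers, with an adjusted p of 0.016 for each of the 4 scores tested, and -0.34, -0.51 and -0.48 without saline replicate 1 (adjusted 0.032); these restate the pattern and test no cause, so a loss of oligodendrocyte transcripts is not excluded for its part. Of the 100 splits, 3 gave as small a camera p for the oligodendrocyte list (real 1.84e-19, smallest other 2.12e-24). That p uses the preset correlation, with which 55 of the other splits also called the list. With an estimated correlation the list was not called. A shallower dissection with less white matter may be the source: of the 3 relations between scores within groups, oligodendrocyte with superficial had r = -0.79 (permutation p = 1e-05, the smallest they can give, adjusted 3e-05; Spearman -0.74, p = 0.00021, adjusted 0.00063; r = -0.7 without the 2 farthest libraries), deep with superficial r = -0.72 (p = 0.00024, adjusted 0.00036; Spearman -0.61, p = 0.0023, adjusted 0.0034; r = -0.55), and oligodendrocyte with deep r = 0.42 (p = 0.048, adjusted 0.048; Spearman 0.35, p = 0.11, adjusted 0.11; r = 0.16). The first 2 relations hold without the farthest libraries and the last rests on them, and because any difference in dissection would coincide with treatment, it and an effect of the inhibitor cannot be told apart.

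Of 219 groups of libraries examined for a value far from the rest, 33 held one, where chance gives about 1 in 20, or 10.9. In PFC after PICK1i, the mitochondrially encoded share of replicate 1 was 16.7% against 8.21 to 11.6%. Replicate 6 had an excitatory score of 7.61, an inhibitory score of 6.32 and an olfactory score of 6.06, with Dusp5 at 40.6, Sik1 at 46.7 and Ptpn1 at 83.4 CPM. Replicate 7 had a leptomeningeal score of 2.37 and Trib1 at 46.2 CPM, and replicate 8 a striatal score of 4.13. In PFC saline libraries, replicate 6 had scores of 4.66 for oligodendrocyte precursors and 4.64 for microglia, replicate 1 a striatal score of 5.72, and replicate 8 Dusp1 at 21.2 CPM. In PFC PSD-95i libraries, replicate 7 had an endothelial score of 5.4 and replicate 6 an olfactory score of 3.16.

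In hippocampus after PICK1i, replicate 7 had scores of 7.33 for thalamic, 4.5 for excitatory and 3.59 for CA1 markers within that tissue, with Dlg4 at 598 CPM. Replicate 2 had a striatal score of 6.82, Nr4a1 at 154 CPM and Arc at 273 CPM, and replicate 8 a choroid plexus score of 4.88. The dentate scores of replicates 2 and 7 were 3.33 and 3.01, against 4.95 to 6.06 in the other PICK1i libraries. The search for single far values did not flag these low dentate scores. Among saline libraries, replicate 1 had a striatal score of 7.46 and a CA1 score of 4.54, replicate 5 a choroid plexus score of 6.15, and replicate 4 Pick1 at 37.7 CPM. Among PSD-95i libraries, replicate 8 had an oligodendrocyte score of 5.86, replicate 2 a microglial score of 4.44 and a CA1 score of 5.85, replicate 7 a striatal score of 3.72, and replicate 4 Pick1 at 58.9 CPM.

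A pair of results differed between tissues in a test of the difference itself. Per1 had a difference of effect of -0.54 after PICK1i (edgeR adjusted p = 0.0282, range 4.26e-05 to 0.389 over the other settings), and 9 of the 100 splits called as many genes for that comparison, up to 38 against the real 1, so chance is not excluded for the count. The immediate early list had a median difference of -0.39 (adjusted p = 0.000502 with an estimated correlation).

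For the remaining comparisons the splits gave these counts. Between the inhibitors in PFC, 4 of the 100 splits gave as many genes as the real 50, with a highest other count of 156 and 6 other splits that called any gene; a split with several times the real count points to a structure among these samples, which was not identified. Where the real count was 0, all 100 splits give as many by construction, which tests nothing. For PSD-95i in PFC 3 other splits called any gene, up to 158. The real count was also 0 for PICK1i, PSD-95i and the comparison of inhibitors in hippocampus and for the PSD-95i effect between tissues, with highest other counts of 1, 0, 25 and 0. For hippocampus against PFC 1 split, the real one, gave 5994 genes, against 1480 at most in the others. For called lists, 95, 26 and 80 of the 100 splits in PFC gave as many as the real 6, 13 and 8 (highest others 21, 22 and 19), and 38, 75 and 24 in hippocampus as many as the real 15, 6 and 16 (highest others 23, 15 and 20), so chance is not excluded for any of these counts of lists. Taken singly, a list called with the preset correlation was also called in 1 to 99 of the other splits of its comparison.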

How the results depend on the processing

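The tests without 5 libraries high in markers of another region, with 2 composition components, with neighbouring replicate numbers summed, of marker scores without 1 PFC saline library, and of the thalamic score and Dlg4 without hippocampal PICK1i replicate 7 were chosen after the data were seen. Counts of 0 in hippocampus were 0 under each gene-level alternative and each omission of 1 library. Where a result moved below, the cause was not tested. Summed pairs leave 4 units per group, and in hippocampal saline they may not join the libraries that stand together in the order of the labels. For PICK1i in PFC, DESeq2 called 47 genes, 2 surrogate variables 61 and summed pairs 17, and omissions gave 19 to 35. For PSD-95i in PFC, DESeq2 called 2, and omissions gave 0 to 2. Between the inhibitors in PFC, an adjusted p under 0.1 gave 86, DESeq2 98 and summed pairs 29, and omissions gave 36 to 83. For the PICK1i effect between tissues, transcripts, no filter and only the groups compared gave 0, DESeq2 2, limma voom 10 and the fit without the 5 libraries 9, and omissions gave 0 to 8 (0 to 0 for PSD-95i). Hippocampus against PFC ran from 5520 to 6494 over omissions and from 5613 to 7335 over the other settings. The filter of 1 CPM keeps more genes than the main one and gave 30 and 50 genes in PFC.

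Same-numbered libraries of different treatments had mean correlations of 0.068, 0.067 and 0.012 in PFC and -0.004, -0.047 and 0.042 in hippocampus. One-sided permutation p ran from 0.11 to 0.7, and 0 to 2 libraries per comparison correlated best with their own number. No pairing of different treatments within a tissue was detected, but with 7 or 8 pairs per comparison it is not excluded. With the replicate block, PICK1i in PFC gave 26 genes (21 shared), PSD-95i 0 and the inhibitors against each other 80 (49 shared).

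Called lists with an estimated correlation, and by fry, were 1 and 1 for PICK1i in PFC, 0 and 0 for PSD-95i and 1 and 1 between inhibitors, and 0 and 0 for each hippocampal comparison. With 2 composition components, 10 lists were called for PICK1i, 13 for PSD-95i and 13 between inhibitors in PFC, and 6, 10 and 6 in hippocampus. Of the main calls (6, 13 and 8 in PFC, 15, 6 and 16 in hippocampus), 5, 5 and 8 kept call and direction in PFC and 1, 6 and 2 in hippocampus. With surrogate variables, 7, 13 and 11 were called in PFC and 8, 5 and 10 in hippocampus, and 6, 5 and 4 of the main calls kept call and direction in PFC and 4, 4 and 5 in hippocampus. Without the 5 libraries, 10 were called between inhibitors in hippocampus, and 5, 11 and 8 kept call and direction in PFC and 6, 5 and 6 in hippocampus. For PSD-95i in PFC these 2 settings, in the order surrogate variables and composition, ended the calls of the glucocorticoid (0.141 and 0.742), clock (0.281 and 0.247), interferon (0.525 and 0.163), precursor (0.277 and 0.0994), superficial (0.0917 and 0.0944) and CA2 and CA3 (0.835 and 0.111) lists, and composition that of glutamate receptors (0.4). Omissions of 1 library gave 6 to 14, 10 to 16 and 6 to 12 lists in PFC and 10 to 19, 5 to 11 and 9 to 18 in hippocampus, in the order PICK1i, PSD-95i and between inhibitors. The likeness of the inhibitors was 0.077 in PFC and, reversed, -0.142 in hippocampus with divided saline libraries, and 0.521 in hippocampus over genes with an unadjusted p under 0.05.

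Results that reversed are given with the camera adjusted p in the other direction, and their cause was not tested. With surrogate variables these were, for PSD-95i in PFC, glutamate receptors (0.877) and leptomeningeal markers (0.000338), for PICK1i in hippocampus oxidative phosphorylation (5.28e-09) and dentate markers (0.501), and between inhibitors in hippocampus scaffold partners (0.908), BDNF signalling (0.957), oxidative phosphorylation (4.98e-07), ribosomal proteins (0.00114), excitatory (0.995) and dentate markers (0.675). With composition components they were leptomeningeal markers for PSD-95i in PFC (1.06e-07), oxidative phosphorylation (0.0178) and thalamic markers (0.867) for PICK1i in hippocampus, and between inhibitors there scaffold partners (0.52), BDNF signalling (0.586), oxidative phosphorylation (1.75e-08), ribosomal proteins (3.01e-07), excitatory and dentate markers (0.529 for both) and CA1 markers (0.943). Without the 5 libraries they were oxidative phosphorylation (7.6e-07) and dentate markers (0.258) for PICK1i in hippocampus, and between inhibitors oxidative phosphorylation and ribosomal proteins (5.49e-05 for both), striatal (0.51) and dentate markers (0.544). Without PICK1i replicate 7 they were oxidative phosphorylation for PICK1i (0.0363) and between inhibitors (0.167), and ribosomal proteins between inhibitors (0.505). Over omissions the adjusted p ran from 2.39e-07 to 0.0363 for oxidative phosphorylation after PICK1i, and between inhibitors from 1.71e-07 to 0.167 for oxidative phosphorylation and from 1.71e-07 to 0.834 for ribosomal proteins. Rgs9 in hippocampus against PFC was -0.30 in DESeq2, and -0.30 (without hippocampal saline replicate 1) to 2.38 over omissions.

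Of 44 calls of named genes, RLE scaling, the filter of 1 CPM and composition components ended 0, surrogate variables 4, limma voom 2, no filter 4, only the groups compared 7, the replicate block 5, transcripts 10 and the fit without the 5 libraries 2. DESeq2 ended 1 and reversed 1, summed pairs ended 9 of 28, and omissions of 1 library ended 80 of 1424 and reversed 1.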

Other observations

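The tests of neighbouring and same-numbered libraries were set before their values were seen, and no test in this part was chosen after its result.

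Neighbouring replicate numbers within a group (1 and 2, 3 and 4, 5 and 6, 7 and 8) had a mean correlation of residual expression of -0.133 over 23 pairs, at the median of random pairings within groups (-0.133, permutation p = 0.49, one-sided). In hippocampal saline, replicate 1 stands alone in the order of the labels. If both tissues follow 1 order, the pairs 1 and 2, 3 and 4, and 5 and 6 there cross the PFC saline pairs. For that group the test may therefore not compare cage mates. Libraries with the same number and treatment in PFC and hippocampus had a mean correlation of 0.053 over 23 pairs, against a median of 0.001 in 10000 random pairings (permutation p = 0.0045, one-sided), and 6 pairs exceeded 0.1. The labels list both tissues in the same order of groups, except that 1 hippocampal saline library stands where PFC has saline replicates 1 and 2. In that order hippocampal saline replicates 2 to 7 stand where PFC has saline replicates 3 to 8. Same-numbered saline libraries may therefore come from different mice, and the test may pair most of them wrongly. That the same mouse gave both tissues may account for the correlation, though not necessarily under 1 number for saline. In that case libraries of different tissues in the fit of all 6 groups are not independent.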
